A study of Mus musculus with 2 samples.

How the data were processed

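Liver RNA was measured by RNA sequencing in 2 libraries. Each library was made from RNA of 3 female NOG-TKm30 mice that was mixed before sequencing, per the labels. The mice, of 22 weeks of age, were given acetoaceto-o-toluidide (AAOT) at 0% for the control pool or 0.3% for the AAOT pool over 4 weeks, per the series' design text. How AAOT was given is not stated in the sources used here. The labels name both NOG and C57BL as the background of the mice, and this was left as it stands. RNA was purified on columns, ribosomal RNA was depleted and directional libraries were made from 200 ng of total RNA, per the labels' protocols.

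The authors deposited 1 table of CPM (read counts scaled to library size) with 15526 gene symbols and 1 column per library. Each column was matched to its library by the code in the sample title. The submitters' processing notes name Trimmomatic 0.38, Bowtie2, RSEM and edgeR and the build mm10, without saying which step each was used for. The annotation is not given in the sources used here. The deposited CPM of each column summed to 1012463 in the control pool and 987690 in the AAOT pool rather than to the same total, so the authors' values include a scaling factor per library, of 0.988 and 1.012. The authors' CPM were whole multiples of 1 step per column for 100% of values, within a relative tolerance of 1e-06. The step gave back 18801241 reads in the control pool and 16528533 reads in the AAOT pool. The smallest sum of reads over both libraries in the table was 2, so genes with fewer reads have no row. The precursor ribosomal transcript Rn45s took 3.89% of reads in the control pool and 4.70% in the AAOT pool, and the 20 most abundant genes took 24.6% and 23.5%.

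With 1 library per group no spread between animals or libraries can be estimated, and no p-value was computed. A count model was therefore not run on the recovered reads. The ratio of the AAOT pool to the control pool was taken as log2((AAOT + 1)/(control + 1)) on the authors' scale, where 1 stands for 1 CPM of the mean column total. This understates the change of genes with low values. Genes were counted as higher or lower when this ratio was at least 2-fold, among genes whose mean over both pools was at least 10 CPM. Folds in the text are plain ratios of CPM. The interval beside a fold is an exact 95% interval of the ratio of 2 read counts (Clopper-Pearson, conditional on their sum). These intervals cover counting error only. They leave out differences between mice, between pools and between library preparations, and they treat reads as independent molecules.

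Gene groups were described with 41 gene lists fixed before the data were examined, as were the ratio, the expression floor, the size counted and the rule for naming genes. For a list with at least 5 members above the floor, the median log2 ratio was set among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. This describes these 2 libraries and is not a test of the treatment. The sums of Mup and globin genes and the splits of the female and male lists were chosen after the values were seen. Of the list symbols that the table did not hold, 3 were found under another symbol of the same gene through RefSeq synonyms. The text names the 12 highest and the 12 lowest genes above the floor, up to 4 members of each list farthest from no change, list members at 1000 CPM or more in either pool, and 14 liver genes chosen in advance. Other genes are named only where the text says so. Some genes that this rule takes are not reported here.

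Gene positions are those of RefSeq on GRCm38, the assembly that the name mm10 refers to. For genes counted as changed and for members of the CAR and PXR, AhR, NRF2, conjugation, acute phase, female and male lists, the share of 50-base stretches of the longest GENCODE transcript that no other gene's transcripts contain was computed. A gene with less than 90% unique stretches has reads that counting could split between copies. This share was available for 247 of 250 genes searched. The steps were tested on simulated reads drawn from the mean levels of the real genes, with 200 genes changed, of which 199 were above the floor in the simulated reads. All 100 genes with a 3-fold change were counted as changed (100%), 0 of 100 with a 1.5-fold change and 0 of 7548 unchanged genes above the floor were. The 95% intervals held the true ratio for 95.5% of the 7747 changed and unchanged genes above the floor. Of 200 random lists of 20 genes, 2.5% fell below percentile 2.5 or above percentile 97.5, where 5% would be nominal. These lists held unrelated genes, so this share does not cover lists of genes regulated together.

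Alternatives were 5 other scalings between the columns, added constants of 0.1 and 5 CPM, expression floors of 1 and 50 CPM and none, sizes of 1.5-fold and 4-fold, and random lists without matching. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.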

Results

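Livers of NOG-TKm30 mice were profiled after 4 weeks with or without acetoaceto-o-toluidide (AAOT), an amide of the aromatic amine o-toluidine. NOG mice are severely immunodeficient, and the TKm30 transgene is a mutant thymidine kinase of herpes simplex virus under a transthyretin promoter. The design has a single comparison, of 1 AAOT library with 1 control library, each a mix of liver RNA from 3 female mice. The libraries held 16528533 and 18801241 reads assigned to genes, respectively. There was no replicate library, so a fold is that of these pools and its interval covers counting error only. Of 15526 genes listed, 7761 had a mean of at least 10 CPM and entered the counts.

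Of the 7761 genes, 60 were at least 2-fold higher in the AAOT pool and 33 were at least 2-fold lower, which together is 1.20%. The median log2 ratio of the 7761 genes was -0.02, with an SD across genes of 0.29. The counting interval excluded equality for all 60 higher and all 33 lower genes, and in simulated reads counting error alone brought 0 of 7548 unchanged genes past 2-fold. At this floor and depth both outcomes follow from the read numbers. Neither covers differences between mice or library preparations. The highest ratios belonged to the cytochrome P450 genes Cyp2c55 and Cyp2b10, the glutathione transferase Gstm3 and the gene model Gm14430. The lowest belonged to the serum amyloid genes Saa2 and Saa1 and the serpin pseudogene Serpina4-ps1. For Gm14430 no share of unique stretches was available, so reads shared with other genes cannot be judged.

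**Figure D1:**
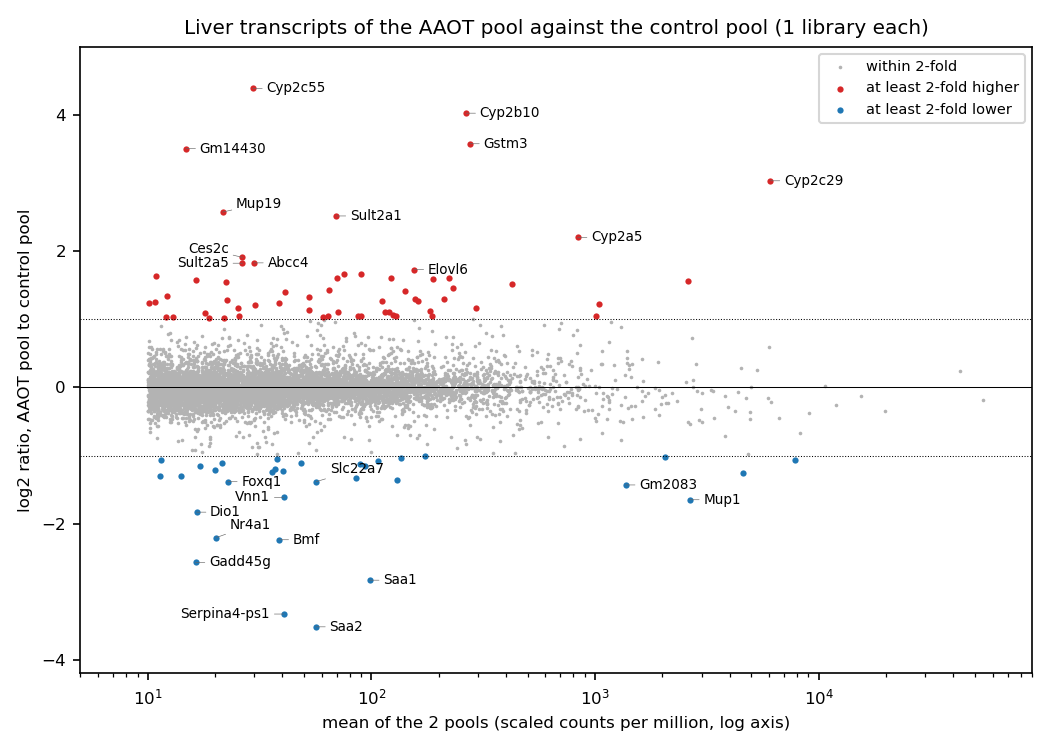
Each point is 1 of the 7761 genes with a mean of at least 10 CPM, placed by the mean of both pools (horizontal, log axis) and by the log2 ratio of the AAOT pool to the control pool (vertical), with dotted lines at 2-fold and the 12 highest and 12 lowest genes named. The 60 genes in red reach a log2 ratio of 4.39 (Cyp2c55), and the 33 in blue reach -3.52 (Saa2).

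Target genes of the xenobiotic receptors CAR and PXR were higher in the AAOT pool. Cyp2b10, the classical marker of CAR activation (chromosome 7, 25897658 to 25926624, GRCm38), was at 29.8 CPM in the control pool and 501 CPM in the AAOT pool, 16.8-fold higher (95% counting interval 15.4 to 18.4). Cyp2c55 (chromosome 19, 39006940 to 39042690) was 32.2-fold higher (22.8 to 47.1), with 33 reads in the control pool and 959 reads in the AAOT pool. Cyp2c29 (chromosome 19, 39287044 to 39330713) was 8.20-fold higher (8.09 to 8.31) and at 10859 CPM was among the most abundant transcripts of the AAOT pool. Cyp2a5 (chromosome 7, 26835339 to 26843264) was 4.61-fold higher (4.48 to 4.75), although only 59.2% of its 50-base stretches are unique to it. Smaller ratios were seen for the PXR target Cyp3a11, at 1.52-fold (1.503 to 1.53), for Cyp2c50, at 1.86-fold (1.82 to 1.90), and for Cyp2c37, at 2.07-fold (2.03 to 2.12). Cyp2c37 and Cyp2c50 also share sequence with related genes, with 69.9% and 83.4% unique stretches. The female-type genes Cyp2b9 and Cyp2b13, neighbours of Cyp2b10 in sequence and named here after their values were seen, were at 1.16-fold (1.13 to 1.19) and 1.12-fold (1.08 to 1.16). Of 18 members of the CAR and PXR list above the floor, 6 were at least 2-fold higher, 0 were at least 2-fold lower and 17 had a ratio above 0. The list median was 0.90 (log2), farther from 0 than that of any of 10000 matched random lists. Because random lists hold unrelated genes, this rank here and below is a description and measures neither chance nor the treatment. The receptors themselves differed less, with Nr1i3 (CAR) 1.22-fold lower (1.15 to 1.30) and Nr1i2 (PXR) 1.20-fold higher (1.11 to 1.31).

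Several glutathione transferases, sulfotransferases and carboxylesterases were higher as well, while other conjugation and hydrolysis enzymes were lower. Gstm3 (chromosome 3, 107963696 to 107969174) was 12.2-fold higher (11.3 to 13.2), and the abundant Gstm1 was 2.96-fold higher (2.92 to 3.002), at 3893 CPM in the AAOT pool. Gsta2 was 3.09-fold higher (2.63 to 3.64). The exporter Abcc4 (Mrp4; chromosome 14, 118482692 to 118707856) was 3.76-fold higher (3.24 to 4.37). These genes belong to the list of targets of NRF2, the regulator of antioxidant defence, in which 7 of 31 members were at least 2-fold higher, 1 was at least 2-fold lower and the median was 0.51. The lower member, named after its values were seen, was Osgin1, at 2.60-fold lower (2.43 to 2.78). The classical NRF2 target Nqo1 was 1.99-fold higher (1.62 to 2.46) but stayed low, at 15.2 CPM in the AAOT pool, and heme oxygenase Hmox1 was 1.27-fold higher (1.11 to 1.45). Among conjugation and hydrolysis enzymes, 6 of 41 were at least 2-fold higher, 0 at least 2-fold lower and 13 below 0, with a median of 0.27. The abundant carboxylesterase Ces3a was the lowest member, at 1.59-fold lower (1.56 to 1.62). The sulfotransferase Sult2a1 was 5.97-fold higher (5.34 to 6.68), its relative Sult2a5 3.77-fold (3.22 to 4.43), the carboxylesterase Ces2c 4.02-fold (3.43 to 4.73) and the glucuronosyltransferase Ugt1a5 3.23-fold (2.97 to 3.50). Gstm3, Gstm1, Gsta2, Sult2a1, Sult2a5, Ces2c, Ces3a and Ugt1a5 each have less than 90% unique stretches, so the split of reads between family members is uncertain.

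The most responsive target of the aryl hydrocarbon receptor (AhR), Cyp1a1, was barely expressed, with 18 reads in the control pool and 29 reads in the AAOT pool, a ratio of 1.79 with an interval of 0.96 to 3.42 that includes equality. Cyp1a2, the constitutive hepatic form and an enzyme that N-hydroxylates aromatic amines, was 1.89-fold higher (1.84 to 1.95). The flavin monooxygenase Fmo2, also in the AhR list, was 1.78-fold higher (1.60 to 1.98). Of 8 AhR list members above the floor, 1 was at least 2-fold higher and 0 lower, the median was 0.47, and 5 of the 8 also stand in another list. This median depended on the expression floor, at 0.81 with a floor of 1 CPM and 0.13 with a floor of 50 CPM. The medians of the NRF2, conjugation and AhR lists each lay above those of all 10000 matched random lists. Transporters showed no common direction, with 9 of 16 above 0 and a median of 0.05 at percentile 85.7 of random lists. Within them the organic anion transporter Slc22a7 (Oat2) was 2.66-fold lower (2.41 to 2.95), while the sterol transporters Abcg8 and Abcg5 were 1.67-fold (1.59 to 1.77) and 1.63-fold (1.54 to 1.72) lower and Slco1a4 was 1.55-fold higher (1.49 to 1.62).

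Genes of fatty acid, triglyceride and cholesterol synthesis were higher in the AAOT pool. The elongase Elovl6 (chromosome 3, 129532386 to 129638495) was 3.35-fold higher (3.15 to 3.57), the lipogenic regulator Thrsp 3.10-fold (2.89 to 3.32), the phosphatidate phosphatase Lpin1 3.05-fold (2.88 to 3.22) and the acetyl-CoA carboxylase Acacb 2.77-fold (2.63 to 2.90). Fatty acid synthase, Fasn, was at 624 CPM in the control pool and 1463 CPM in the AAOT pool, 2.34-fold higher (2.29 to 2.40). Of 22 members of the list, 7 were at least 2-fold higher, 0 lower and 20 above 0, with a median of 0.55. The desaturase Scd1 was abundant and nearly equal in the pools, at 1.02-fold (1.01 to 1.03). Srebf1, which encodes the SREBP-1 regulator of these genes and is named after its values were seen, was 1.45-fold lower (1.41 to 1.499). The transcription factor gene Mlxipl of the same list, also named after its values were seen, was 1.67-fold higher (1.59 to 1.75). In the cholesterol list 6 of 23 were at least 2-fold higher, 0 lower and 22 above 0, with a median of 0.74. Its members included Mvd, at 3.54-fold (2.78 to 4.55), Nsdhl, at 2.38-fold (2.09 to 2.72), and Fdps, at 2.18-fold (2.002 to 2.37). Both medians lay above those of all 10000 matched random lists. Targets of the fatty acid receptor PPARalpha went the other way as a list, with 23 of 30 members below 0 and a median of -0.23, below all random lists, though only 1 was at least 2-fold lower. That member was the pantetheinase Vnn1, 3.17-fold lower (2.80 to 3.60). Cyp4a14 was 1.51-fold lower (1.47 to 1.56), while Acot3 was 1.66-fold higher (1.53 to 1.79) and Angptl4 1.504-fold higher (1.42 to 1.60). Ppara itself was 1.47-fold lower (1.42 to 1.52).

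Acute phase genes as a list were lower in the AAOT pool. Saa2 (chromosome 7, 46751833 to 46754313) was at 105 CPM in the control pool and 8.25 CPM in the AAOT pool, 12.7-fold lower (10.7 to 15.2), and Saa1 (chromosome 7, 46740497 to 46743181) was 7.38-fold lower (6.64 to 8.21). These neighbours share sequence, with 68.2% and 67.9% unique stretches. Lcn2 was 2.67-fold lower (2.18 to 3.29), haptoglobin Hp 1.72-fold lower (1.68 to 1.75) and Itih3 1.68-fold lower (1.64 to 1.72). Of 25 acute phase genes 3 were at least 2-fold lower, 2 at least 2-fold higher and 19 below 0, with a median of -0.33. The 2 higher members were the metallothioneins Mt2, at 2.62-fold (2.09 to 3.30), and Mt1, named after its values were seen, at 2.33-fold (2.02 to 2.70). Secreted hepatocyte proteins were lower by small ratios in nearly all cases, with 32 of 33 below 0, none past 2-fold and a median of -0.22. Albumin, Alb, was 1.13-fold lower (1.13 to 1.14), transthyretin, Ttr, 1.28-fold (1.27 to 1.30), Apoa1 1.63-fold (1.62 to 1.65) and Ahsg 1.60-fold (1.58 to 1.61). Both medians lay below those of all 10000 matched random lists. The 10 major urinary protein (Mup) genes above the floor, grouped after their values were seen, summed to 15536 CPM in the control pool and 7581 CPM in the AAOT pool, a 2.05-fold lower sum, with 8 of 10 lower. Mup1 was 3.14-fold lower (3.09 to 3.19) and Mup19 6.86-fold higher (5.56 to 8.55), but 5.24% and 0% of their stretches are unique, so values of single Mup genes are uncertain.

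**Figure D2:**
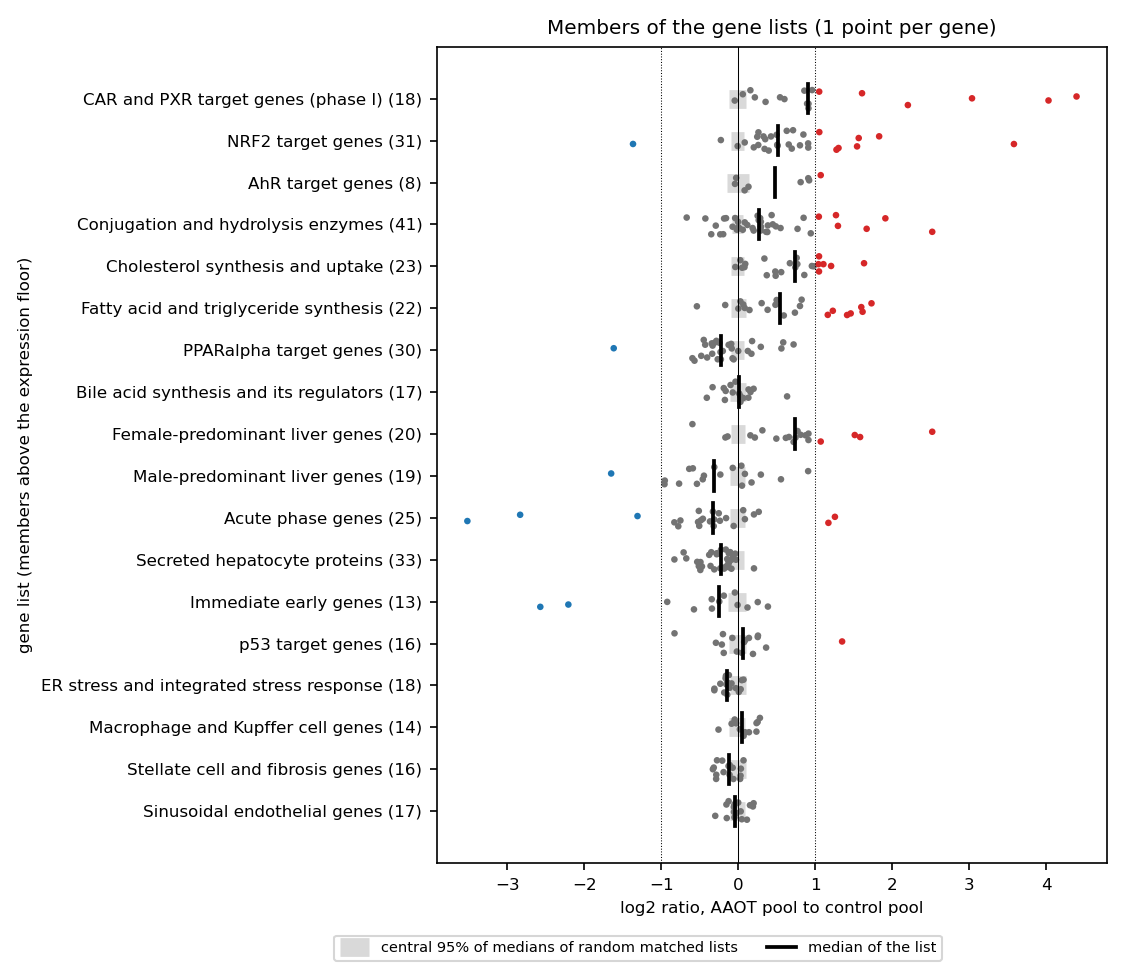
Each point is a gene of a list, placed by its log2 ratio of the AAOT pool to the control pool (horizontal), with lists on the vertical axis and the number of members above the floor in parentheses. Red and blue points are at least 2-fold higher and lower, black bars are list medians and grey bars hold the central 95% of medians of 10000 matched random lists. Among the lists drawn, medians run from -0.33 for acute phase genes to 0.90 for CAR and PXR targets, and the macrophage, stellate cell and sinusoidal endothelial lists have medians of 0.05, -0.12 and -0.04.

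Genes with female-predominant liver expression were higher and those with male-predominant expression lower, although all mice were female. Sult2a1, Prom1, at 3.25-fold (2.69 to 3.96), and Cyp2a4, at 2.86-fold (2.76 to 2.97), led the female list, although 62.0% of the stretches of Cyp2a4 are unique. In this list 4 of 20 were at least 2-fold higher, 0 lower and 17 above 0, with a median of 0.73. Of these 20 genes, 8 also stand in the CAR and PXR, AhR, NRF2 or conjugation lists. The other 12 had a median of 0.64, above all random lists, with 9 of 12 above 0. This split, made after the values were seen, drops only genes named in those lists. The 12 still hold Cyp2a4, with only 62.0% unique stretches, so reads shared with related genes are not removed. In the male list 1 of 19 was at least 2-fold lower, 0 higher and 12 below 0, with a median of -0.31. The epidermal growth factor receptor Egfr was 1.95-fold lower (1.87 to 2.02) and Rarres1 1.95-fold lower (1.82 to 2.09), while Gstp1 was 1.88-fold higher (1.81 to 1.95) with 37.7% unique stretches. Without Mup genes the median of 15 members was -0.23. Pericentral hepatocyte genes were lower by small ratios, with 18 of 23 below 0, none past 2-fold and a median of -0.21, below all random lists. They included Slc13a3, at 2.001-fold lower (1.78 to 2.25) and just inside the limit after the added constant, and Lgr5, at 1.75-fold lower (1.42 to 2.18). Glul was 1.31-fold lower (1.28 to 1.33) and Cyp2e1 1.36-fold lower (1.35 to 1.37). Cyp1a2, 1 of 5 pericentral members above 0, went the other way, at 1.89-fold higher (1.84 to 1.95). Periportal genes had a median of 0.05, at percentile 91.6 of random lists.

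Bile acid genes had a median of 0.01, at percentile 65.5 of random lists. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at 131 CPM and 137 CPM, a ratio of 1.05 (0.99 to 1.11), and 0 of 17 list members passed 2-fold. In gluconeogenesis and amino acid catabolism 19 of 28 were above 0 with a median of 0.19, at percentile 99.99 of random lists. Igfbp1 was 2.02-fold lower (1.91 to 2.13), the tryptophan dioxygenase Tdo2 1.82-fold lower (1.77 to 1.86) and the coactivator Ppargc1a 2.18-fold higher (1.78 to 2.66). Among heme and iron genes 1 of 29 was at least 2-fold higher, with a median of -0.06. Alas1, the rate-limiting enzyme of heme synthesis, was 2.003-fold higher (1.92 to 2.09), just inside the limit after the added constant. The hepcidin gene Hamp was 1.19-fold lower (1.14 to 1.23) and its copy Hamp2 2.08-fold higher (1.90 to 2.28), with 84.5% unique stretches.

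Among p53 targets 1 of 16 was at least 2-fold higher and 0 lower, with a median of 0.06. The stress cytokine Gdf15 was 2.79-fold higher (2.25 to 3.48), while Cdkn1a, which encodes the p21 inhibitor, was 1.84-fold lower (1.55 to 2.18). Of 39 cell cycle genes 7 reached the floor, 0 passed 2-fold and the median was -0.03. This median changed sign under other scalings and with the floor, at 0.07 with a floor of 1 CPM, 0.19 with a floor of 50 CPM and 0.11 without a floor. The proliferation marker Mki67 had 56 reads in the control pool and 70 reads in the AAOT pool, a ratio of 1.39 with an interval of 0.96 to 2.01, while the nucleotide synthesis genes Tyms and Tk1 were 1.55-fold (1.44 to 1.66) and 1.37-fold (1.18 to 1.59) higher. Replication-dependent histone genes were lower, with 7 of 61 above the floor, 7 of 7 below 0 and a median of -0.52, such as Hist1h1e at 1.71-fold lower (1.44 to 2.04). The histone median was -0.25 with a floor of 1 CPM and -0.15 without a floor. Genes of the unfolded protein and integrated stress responses had a median of -0.14, at percentile 0.75 of random lists, with 14 of 18 below 0 and 0 of 18 past 2-fold. Interferon-stimulated genes had a median of 0.08, at percentile 98.3 of random lists matched on expression, with 0 of 17 past 2-fold, and MHC genes a median of -0.02, which changed sign under 2 other scalings, with 0 of 8 past 2-fold.

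Macrophage and Kupffer cell genes had a median of 0.05, which was -0.012 with a floor of 50 CPM, with 0 of 14 past 2-fold and Adgre1, which encodes F4/80, at 1.23-fold (1.07 to 1.41). Sinusoidal endothelial genes had a median of -0.04, which changed sign under 1 other scaling, with 0 of 17 past 2-fold, and stellate cell and fibrosis genes a median of -0.12 with 0 of 16 past 2-fold, at percentile 2.94 of random lists. The stellate cell median was -0.23 with a floor of 1 CPM and -0.19 without a floor. Erythroid genes had a median of 0.17 over 5 members, which was 0.08 without a floor, and the globin genes summed to 302.7 CPM in the control pool and 334 CPM in the AAOT pool. Of 4 cholangiocyte genes above the floor 1 was at least 2-fold higher, Prom1, which is also in the female list, while Spp1 was 1.31-fold lower (1.16 to 1.48). Of 25 lymphocyte and NK cell genes 10 were listed and 1 reached the floor, the DNA repair kinase gene Prkdc, at 22.6 CPM and 23.2 CPM. Of 18 neutrophil genes 11 were listed and 1 reached the floor, Lcn2, which hepatocytes also make. The neutrophil genes S100a8 and S100a9, named after their values were seen, had 4 and 5 reads in the control pool and 8 and 4 reads in the AAOT pool. No pancreas gene reached the floor (0 of 5 listed), and of 2 adipocyte genes above it Car3, which hepatocytes also express, was at 1.26-fold (1.24 to 1.29) and Lpl at 1.002-fold (0.86 to 1.17). Of the fetal liver and hepatocarcinogenesis genes 3 of 20 listed reached the floor and 0 passed 2-fold.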

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

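The counts of 60 higher and 33 lower genes stayed within 1.5 times under each of the 5 other scalings (1 of them, without Rn45s, chosen after seeing the data) and both other added constants (49 to 66 higher, 27 to 35 lower). The scalings moved the median of all genes by at most 0.05 (log2). Counts followed the limits set: 161 higher and 108 lower at 1.5-fold, 8 and 6 at 4-fold, 90 and 55 with a floor of 1 CPM, 37 and 15 with a floor of 50 CPM, and 94 and 60 without a floor. In other settings chosen after seeing the data, 39 of the higher genes and 24 of the lower genes had at least 90% unique sequence, and 47 and 25 had their whole counting interval beyond 2-fold. No list median outside the central 95% of random lists and no named gene past 2-fold changed its sign under any setting run. For the genes this was bound to hold, because the scalings moved ratios by far less than 2-fold and an added constant cannot change a sign. Of list medians outside the central 95%, those of the AhR, histone and immediate early genes moved by over 1.5 times with the floor, as given beside them, and 3 small ones moved with scaling: without Rn45s the stress response median was -0.10, the interferon median 0.13 and the oxidative phosphorylation median -0.011. Inside the central 95%, the cell cycle, macrophage, stellate cell, erythroid and clock medians moved by over 1.5 times with the floor, as given beside them, as did the p53 median, to 0.19, and the heme and iron median, to -0.11, at 50 CPM. Medians near 0, such as those of the MHC, sinusoidal endothelial, bile acid and nuclear receptor lists, also moved by such factors with scaling and with the floor. Without Rn45s the heme and iron median was -0.017 and the p53 median 0.11. Matching random lists on expression mattered for 3 lists: without it interferon-stimulated genes went from percentile 98.3 to 96.8, stellate cell genes from 2.94 to 2.12 and oxidative phosphorylation genes from 1.28 to 3.78. No paired analysis was possible because each group has 1 library and the labels give no replicate numbers, and for the same reason no replicate could be left out. Depth limits genes of few reads such as Cyp1a1, with 18 and 29 reads, and the spread between mice was not measured.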

Other observations

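All tests of explanations in this part were chosen after the ratios were seen, as were the fasting and clock phase lists, while the 41 other gene lists were fixed before. Several other gene groups differed between the pools. Immediate early genes were lower in the AAOT pool, with 2 of 13 at least 2-fold lower and a median log2 ratio of -0.25, which was -0.04 without an expression floor. Gadd45g was 7.17-fold lower (95% counting interval 5.55 to 9.39) and the orphan receptor Nr4a1 5.16-fold lower (4.21 to 6.38), while Dusp1 was 1.92-fold lower (1.75 to 2.11). Among clock genes Per3 was 2.12-fold higher (1.795 to 2.498) and Per1 1.90-fold higher (1.70 to 2.12), whereas Arntl and Nr1d1, named after their values were seen, were at ratios of 0.98 (0.82 to 1.17; its sign changed under other scalings) and 0.93 (0.87 to 0.99). The clock list as a whole had a median of 0.09, at percentile 97.4 of random lists, and this median was 0.25 with a floor of 1 CPM, 0.24 without a floor and 0.014 with a floor of 50 CPM. Heat shock and proteasome genes were higher by small ratios, with 16 of 18 above 0, 0 past 2-fold and a median of 0.25, led by Hsp90aa1 at 1.40-fold (1.33 to 1.47).

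After subtraction of the median of genes of like transcript length, the median of the histone genes was -0.45. Nuclear genes of oxidative phosphorylation had a median of -0.06 over 77 genes, at percentile 1.28 of random lists. Ribosomal protein genes had a median of -0.02 over 76 genes and nuclear receptor genes were above 0 for 11 of 22, and both medians changed sign under other scalings. No mitochondrially encoded gene was listed, and 0 of 9 listed small nucleolar and nuclear RNA genes reached the floor. Outside the lists, the 12 lowest genes included the pro-apoptotic gene Bmf, 5.002-fold lower (4.32 to 5.81), the deiodinase Dio1, 3.94-fold lower (3.20 to 4.89), and the transcription factor gene Foxq1, 2.74-fold lower (2.34 to 3.23).

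The higher CAR and PXR target genes were weighed against 1 technical explanation. If reads shared between related P450 genes made the pattern, members with unique sequence would not show it, but the 8 members with at least 90% unique stretches had a median of 1.28 against 0.88 for the 10 others. No biological explanation was tested, and with 1 pool of 3 mice per group the AAOT treatment and other differences between the pools or library preparations all stay open.

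The higher lipid synthesis genes raise the question of when the mice last ate and at what hour tissue was taken. A more fed AAOT pool would have lower fasting-induced genes, and 16 of these had a median of -0.20 with quartiles of -0.37 and 0.21, neither clearly lower nor near 0 throughout. A later hour would separate evening from morning clock genes, and medians of 7 evening and 4 morning genes differed by 0.40. A resampling interval over genes was 0.23 to 1.03, which leaves the size open. It treats clock genes as independent and does not measure the spread between mice or pools, so it cannot decide the question. Feeding state and time of day therefore stay possible explanations, as does the treatment itself, and the sources used here do not give feeding state or hour. Lower Srebf1 beside higher Fasn, Elovl6 and Mlxipl is a feature that replicated animals could check.

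The lower acute phase genes were weighed against 3 explanations. For less RNA from macrophages or Kupffer cells, their 14 genes had a lower quartile of -0.045, above the acute phase median of -0.33. RNA of these cells as a list was thus not lower by that size. Acute phase members such as Fgb and C3 also stand in the secreted hepatocyte list, and for such genes this comparison is no test. Signals from these cells to hepatocytes were not measured, so a part for them is not decided. A length trend existed across 7733 genes (Spearman's rho 0.10, with genes not independent replicates), but after its removal the acute phase median was -0.30. The lowest and highest of the 20 length bins had medians of only -0.07 and 0.03, so this removal could move a list median little. Lengths were those of the longest transcript of each gene. A single control mouse with a high response stays open, because RNA was mixed before sequencing. Such a mouse would need 298 CPM of Saa2 if the others equalled the AAOT pool, so it cannot be told apart from a lower level in all AAOT mice.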
